A study of Mus musculus with 2 samples.

How the data were processed

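Total RNA of the adrenal gland was measured in 2 mice of 1 group. Per the labels, 300 ng of RNA entered each library, the extraction and directional library kits were named by their manuals, ribosomal RNA was reduced, and ERCC spike-in RNA was added. Per the file headers and the deposited text files, the tables use the mm10 assembly with GENCODE annotation M21. The names of the aligner and quantifiers are not given in the sources used here.

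Per the file headers, the gene and transcript tables hold expected counts, which are estimated and need not be whole, and the deposited text files say that they were made from transcriptome alignments. The same deposited tables give TPM, scaled over all features of the table, and FPKM, scaled to length and counts. Per the file headers, the transcript tables give each transcript's percent of its gene. A second deposited transcript table, made straight from the reads and a transcript index, holds estimated counts and TPM. The deposited gene tables also give a posterior SD of each count. Expected counts split reads between near-identical genes by a model, so values for such genes are uncertain. Reads of CAST alleles were placed on a reference of another strain.

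All 55536 gene identifiers matched the annotation. Rows that name no gene stayed out of library sizes and tests. ERCC rows held 0.502% of the counts in mouse 1 (95% Wilson interval 0.499% to 0.504%) and 0.526% in mouse 2 (0.524% to 0.529%). The 26248 numbered rows held 1.84e-05% and 8.53e-06%, and the phiX row held 354 and 238 counts. Depth was 36558609 and 32192201 expected counts in genes, for mouse 1 and mouse 2. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

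Levels are the mean and SD of the deposited TPM. The log2 ratio of mouse 2 to mouse 1 used expected counts scaled by TMM in edgeR 4.0.16 (R 4.3.3) with a prior count of 2, among genes with a mean of at least 10 counts, and a threshold of 2-fold. Expected counts were rounded to whole numbers for the exact two-sided binomial test, adjusted by Benjamini-Hochberg at 0.05, and for the edgeR dispersion, which was fitted with an intercept only. With 1 group and 2 mice no test between groups was made. Each of 29 lists, fixed before the data were examined, was summarised by its median, set among the medians of 10000 random lists matched in 20 expression bins. For lists of 6 or more tested genes an exact 95% interval of the median was taken from the ordered members, which are genes and not replicates. For shorter lists, the counting interval of the middle members was used to judge the alternatives. The second table was summed to genes and compared with the first on TPM plus 0.1. Of the second quantification, 86 genes had no row and were left out of that comparison. Copies of mitochondrial genes were paired with BLAST 2.17.0. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

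The genes named followed a rule fixed before the data were examined. It took the 4 members of highest mean TPM of each list, with the range of every member for lists of other tissues and Y-linked genes, and the 10 genes of highest mean TPM. It also took the 8 largest log2 ratios in each direction among genes with at least 100 counts, and the 5 largest ratios in each direction between the quantifications at 10 TPM or more, leaving out clone and numbered names. The leading transcripts of 13 genes and the genes Xist, App, Thy1 and Cyp17a1 were always taken. A further item that the rule names is not reported here. Among genes with at least 100 counts at least 2-fold apart, 12 higher and 15 lower in mouse 2 had such clone or numbered names. Other genes named were chosen after their values were seen.

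The log2 ratio and the binomial test were tried on simulated data. Counts were drawn for 17666 genes from their means over the mice, and 200 of these genes were changed. The draw held counting noise only, with no spread between mice, and was scaled to total counts. TMM scaling, the dispersion fit and the splitting of reads between genes were therefore not tried. At 3-fold, 87.9% of 66 changed genes passed the binomial test and 95.5% reached 2-fold. At 2-fold, 71.6% of 67 passed and 50.7% reached 2-fold. At 1.5-fold, 53.7% of 67 passed and 5.97% reached 2-fold. Of 17466 unchanged genes, 7 passed the binomial test. The draw follows the assumption of that test, so this low number was largely fixed in advance.

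The alternatives were total count, median-of-ratios and ERCC scaling, other count filters, a prior count of 0.5, the second quantification, nuclear protein-coding genes alone, FPKM, other TPM thresholds and pseudocounts, and each mouse alone. A filter on the deposited posterior SD was added after seeing the data, as were 6 gene lists: brown fat, fat synthesis, adipocyte genes outside the fixed list, B lineage, neutrophils and platelets, and mesothelium.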

Results

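Total RNA was sequenced from the adrenal glands of female mice from a cross of the 5xFAD strain, a transgenic model of Alzheimer's disease, with the wild-derived CAST strain. The labels gave 1 group, with mice of 8 to 10 months of age and 2 biological replicates, here called mouse 1 and mouse 2 after their replicate numbers. Both carried the same donor identifier, so that they were separate animals rests on the replicate numbers alone. The gene tables held 36558609 expected counts in genes for mouse 1 and 32192201 for mouse 2. No second group was analysed here, so the levels in the gland, the differences between the mice, and the agreement of 2 quantifications of each library are described. A mean ± SD is over both mice (n = 2). TPM was not rescaled between the mice, so its SD also holds differences in library composition.

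The transcripts of the steroid-producing cortex were among the most abundant messenger RNAs of the gland. Star, which moves cholesterol into mitochondria (chromosome 8, 25806555 to 25815982, mm10), stood at 5434 ± 435 TPM (SD, n = 2). Hsd3b1 stood at 5386 ± 407 TPM and Cyp21a1 at 4989 ± 192 TPM, both enzymes of corticosteroid synthesis. Cyp11b1, which makes corticosterone (chromosome 15, 74834125 to 74841643), stood at 2784 ± 21.9 TPM. Of the 18 genes of the steroid hormone synthesis list, 17 reached 1 TPM in both mice. The exception was Cyp17a1, the 17-alpha-hydroxylase, at 0.51 ± 0.028 TPM.

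Zone markers were present at different levels. Cyp11b2, the aldosterone synthase of the zona glomerulosa, stood at 172 ± 15.8 TPM, and Agtr1a, an angiotensin receptor, at 81.5 ± 0.948 TPM. Cyp11b2 was placed at 430 and 400.3 TPM in mouse 1 and mouse 2 by the second quantification, against 183 and 161 TPM in the first. The potassium channel gene Kcnk3 stood at 502 ± 44.9 TPM. Akr1c18, a marker of the X-zone, the inner cortical zone of female mice, stood at 320.5 ± 26.1 TPM, and Cyp2f2 at 168 ± 18.1 TPM. All 5 members of the X-zone list reached 1 TPM in both mice.

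The medulla was represented by all 23 genes of the chromaffin cell list. Chga and Chgb, which encode granins of the secretory vesicle, stood at 727 ± 34.1 and 641 ± 21.02 TPM. Th, the rate-limiting enzyme of catecholamine synthesis, stood at 246 ± 8.23 TPM, Dbh at 138 ± 1.29 TPM and Pnmt, which makes adrenaline, at 258 ± 42.3 TPM. Npy stood at 289 ± 21.6 TPM and Scg2 at 323 ± 8.23 TPM.

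**Figure D1:**
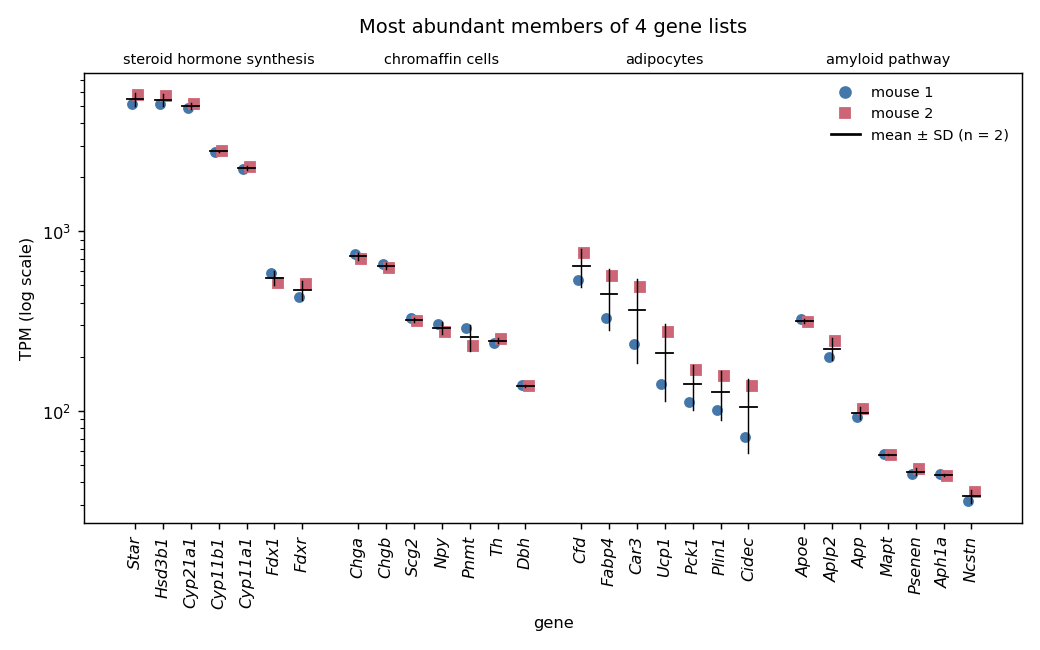
TPM on a log axis of the 7 most abundant members of each of 4 gene lists, with mouse 1 as circles, mouse 2 as squares, and the mean and SD of both mice (n = 2) as bars. The steroid synthesis genes reach a mean of 5434 TPM, and the adipocyte genes are higher in mouse 2.

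Markers of other cells were also measured. The endothelial list had a median of 18.8 TPM and its top member Plvap stood at 60.6 ± 6.51 TPM. The macrophage and lymphocyte list had a median of 9.14 TPM, led by Cd74 at 88.7 ± 20.01 TPM. The capsule and fibroblast list had a median of 10.96 TPM, with Mgp at 51.2 ± 1.87 TPM. The Schwann and sustentacular cell list had a median of 0.56 TPM. Adipocyte genes were abundant, with Cfd at 644 ± 156 TPM, Fabp4 at 448 ± 168 TPM and Ucp1, the uncoupling protein of brown fat, at 209 ± 95.5 TPM.

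Markers of neighbouring organs were scarce. Of the 10 kidney genes, 1 reached 1 TPM in both mice, Cyp4b1 at 14.8 ± 0.566 TPM, and the other members ranged up to 0.22 TPM, the mean of Aqp2. Of the 11 liver and pancreas genes, Apoa2 alone reached 1 TPM in both mice, at 1.04 ± 0.014 TPM. Alb stood at 0.46 TPM in mouse 1 and 1.89 TPM in mouse 2, with 36 and 113 counts. None of the 9 skeletal muscle genes did. Of the 10 ovary and gonad-like genes, Inha alone did, at 8.98 TPM in both mice. Xist, the RNA of the inactive X chromosome, stood at 45.5 ± 4.19 TPM, and the Y-linked genes Ddx3y, Eif2s3y and Uty had at most 3 counts in a library. A count of 0 allows up to 0.0821 CPM in mouse 1 and 0.0932 CPM in mouse 2, for counting error only.

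App, the mouse counterpart of a human gene carried by the 5xFAD strain, stood at 97.3 ± 7.64 TPM (chromosome 16, 84949685 to 85173766). Thy1, whose promoter drives the transgenes of that strain, stood at 15.8 ± 0.106 TPM. The second quantification placed Thy1 at 25.2 TPM in mouse 1 and 28.3 TPM in mouse 2. The transgenes are human sequences, and any reads from them were not told apart from those of the mouse genes here. The labels name the cross, and whether each mouse carried the transgenes was not checked. All 14 members of the amyloid pathway list reached 1 TPM in both mice, led by Apoe at 317 ± 8.80 TPM and Aplp2 at 222 ± 31.0 TPM.

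Structural RNA took a large part of TPM, which is scaled to length and so gives short RNAs more weight than their counts. Of the expected counts in genes, nuclear protein-coding genes held 67.2% in mouse 1 and 69.1% in mouse 2. The miscellaneous RNA class, which includes Rn7s1, Rn7s2 and Rn7sk, held 10.4% and 8.69%, and mitochondrial ribosomal RNA 7.57% and 7.65%. The near-identical 7SL RNA genes Rn7s1 and Rn7s2, which share their reads, took 40.7% of TPM in mouse 1 and 37.6% in mouse 2. The 10 most abundant genes together took 55.4% ± 2.28 of TPM. They also included Rn7sk at 47000 ± 5964 TPM and the mitochondrial ribosomal RNAs mt-Rnr1 at 38613 ± 756 TPM and mt-Rnr2 at 25938 ± 3754 TPM. The others were Gm26917 at 14405 ± 370 TPM, mt-Co1 at 7999 ± 1244, Rpph1 at 6994 ± 223, mt-Co2 at 6076 ± 5499 and Gm10925 at 8084 ± 1197. Gm10925, on chromosome 1, is identical over 678 bases to mt-Atp6. The second quantification placed Gm10925 at 104 TPM in mouse 1 and 131 TPM in mouse 2, so its part of the share is uncertain. Nuclear protein-coding genes took 29.5% of TPM in mouse 1 and 32.3% in mouse 2. The TPM of a messenger RNA is therefore lower here than in a library without structural RNA. Since this share differed between the mice, an SD of TPM is not a gene's spread after TMM scaling. Cyp11b1, for example, had an SD of 21.9 TPM and a log2 ratio of -0.16, while Hsd3b1 had 407 TPM and -0.0034. In all, 13136 genes reached 1 TPM in both mice, of which 11913 were nuclear protein-coding genes.

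The second comparison was between the 2 mice. Immediate early genes, which respond within minutes to stimulation, were lower in mouse 2. All 18 members lay below a log2 ratio of 0, with a list median of -0.69. The transcription factor genes Fos (-3.15), Junb (-2.72) and Egr1 (-2.44) were the members at least 2-fold apart. Of the 4 most abundant members, Nr4a1 stood at -0.82, Jun at -0.28, Jund at -0.11 and Fosl2 at -0.05. Fos, for example, had 612 counts in mouse 1 and 61 in mouse 2. Red blood cell genes were lower as well, all 6 tested members, with a list median of -1.02, Hba-a1 at -1.11 and Hbb-bs at -0.99.

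Adipocyte genes were higher in mouse 2. All 11 tested members lay above 0, with a list median of 0.70 and none at 2-fold or more. Car3 stood at 0.87, Ucp1 at 0.79, Fabp4 at 0.61 and Cfd at 0.33. Outside that list, the largest ratios toward mouse 2 included Ly6k at 1.58, Scd1, a fatty acid desaturase, at 1.38, Dio2, a thyroid hormone deiodinase, at 1.21 and Ppargc1a, a transcriptional coactivator, at 1.20. The transcriptional repressor gene Bcl6 and Fabp5 stood at 1.19, and Tmem120b at 1.18. Among the largest ratios toward mouse 1 were also Gadd45b at -1.48 and Tgm3 at -1.47.

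The immediate early and red blood cell medians lay below all 10000 random lists matched on expression, and the adipocyte and circadian clock medians above all of them. The clock list had a median of 0.24 with an interval of -0.06 to 0.32, which includes 0. Of its 16 members 12 were higher, with Dbp at 0.23 and Nr1d1 at 0.28, and 4 lower, with Per1 at -0.10. These percentiles describe the libraries and are no test between conditions.

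Steroid synthesis genes went both ways, 8 of 18 higher and 10 lower in mouse 2, with a list median of -0.04 at percentile 22.6 of the random lists. Star stood at 0.06 and Cyp11a1 at -0.13, while Mrap stood at -0.50, Fdx1 at -0.42, Cyp11b2 at -0.36, Hsd3b6 at 0.36 and Hsd11b1 at 0.32. None of the 18 was 2-fold apart, and 12 differed beyond counting noise, as did 3770 of all 17666 genes tested. Abundant genes pass the binomial test at small ratios, as Star did at 0.06, so the 12 partly reflect abundance. The zona fasciculata list had a median of -0.13, at percentile 0.75, with Akr1b7 at -0.85 and the lipoprotein receptor gene Scarb1 at -0.63, while Hsd3b1 and Cyp21a1 were within 0.1 of 0. The chromaffin list had a median of -0.11, at percentile 0.09, with 19 of 23 members below 0, and Pnmt stood at -0.51. The cholesterol synthesis list had a median of -0.13, at percentile 0.02, with 6 of 18 members higher and an interval of -0.35 to 0.06, which includes 0. The ribosomal protein list had a median of -0.12, at percentile 0.19, with 15 of 16 members lower. The structural and nuclear RNA list had a median of -0.21, at percentile 0.01, with an interval of -0.64 to 0.13, and Rn7sk at -0.43 but mt-Rnr2 at 0.12. The X-zone list had a median of 0.18, at percentile 98.6, with 3 of 5 members higher. That median is the value of Thrb, and the 2 most abundant members did not share it, with Akr1c18 at -0.01 and Cyp2f2 at -0.40. The capsule and fibroblast, glucocorticoid target and interferon response lists had medians of -0.10, -0.09 and -0.15, at percentiles 1.11, 1.64 and 1.40, with intervals that include 0. The lists not given here with a percentile lay between percentiles 4.96 and 94.4. The heat shock list had a median of -0.07 and the amyloid pathway list -0.05. App stood at -0.02.

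**Figure D2:**
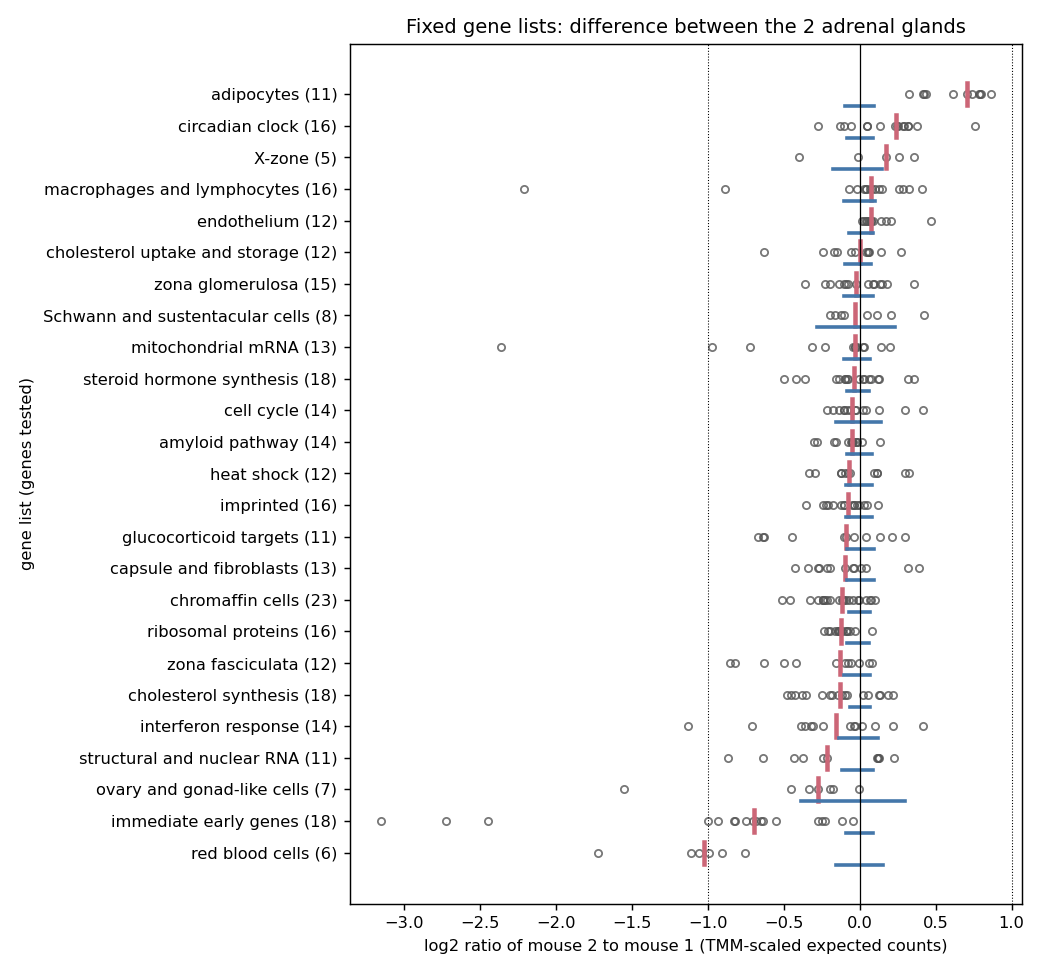
Log2 ratio of mouse 2 to mouse 1 for each tested gene of the fixed lists with at least 5 tested genes, as circles, with the list median in red and the central 95% of medians of 10000 matched random lists as a blue line beneath it. Dotted lines mark 2-fold. The adipocyte median of 0.70 and the red blood cell median of -1.02 lie at the ends.

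Among 17666 genes with a mean of at least 10 expected counts, 204 were at least 2-fold higher in mouse 2 and 319 at least 2-fold lower. Counting noise alone brought 96 of 17466 unchanged simulated genes to 2-fold. Among genes with at least 100 counts, 28 were higher and 37 lower. An exact binomial test on the counts, adjusted by Benjamini-Hochberg, found 3770 genes that differed beyond counting noise. Its p-values measure only the difference between these 2 libraries, which may be technical, since 2 preparations of 1 animal could also differ beyond counting noise. Of the genes 2-fold apart, 95 of the 204 higher and 154 of the 319 lower were also 2-fold apart in the same direction in the second quantification. The biological coefficient of variation was 0.114, and it was 0.0903 among nuclear protein-coding genes.

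Some of the largest ratios lay on genes with near-identical copies. The mitochondrial gene mt-Co2 had 236928 counts in mouse 1 and 41982 in mouse 2, and mt-Co3 had 197159 and 91589. Their copies on chromosome 1, chosen after their values were seen, went the other way. Gm28661 (24614885 to 24615565), identical over 681 bases to mt-Co2, had 14848 and 193267 counts. Gm28437 (24613189 to 24613971), identical over 783 bases to mt-Co3, had 2229 and 113022. The second quantification placed mt-Co2 at a log2 ratio of -0.51 in place of -2.36. The ribosomal protein pseudogene Rpl7a-ps11 was listed at 1038 counts in mouse 1 and 0 in mouse 2, and Rps12l1 at 0 and 289 counts. Atp5g2 stood at -1.73, and at -0.18 in the second quantification. Values for such genes are uncertain.

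**Figure D3:**
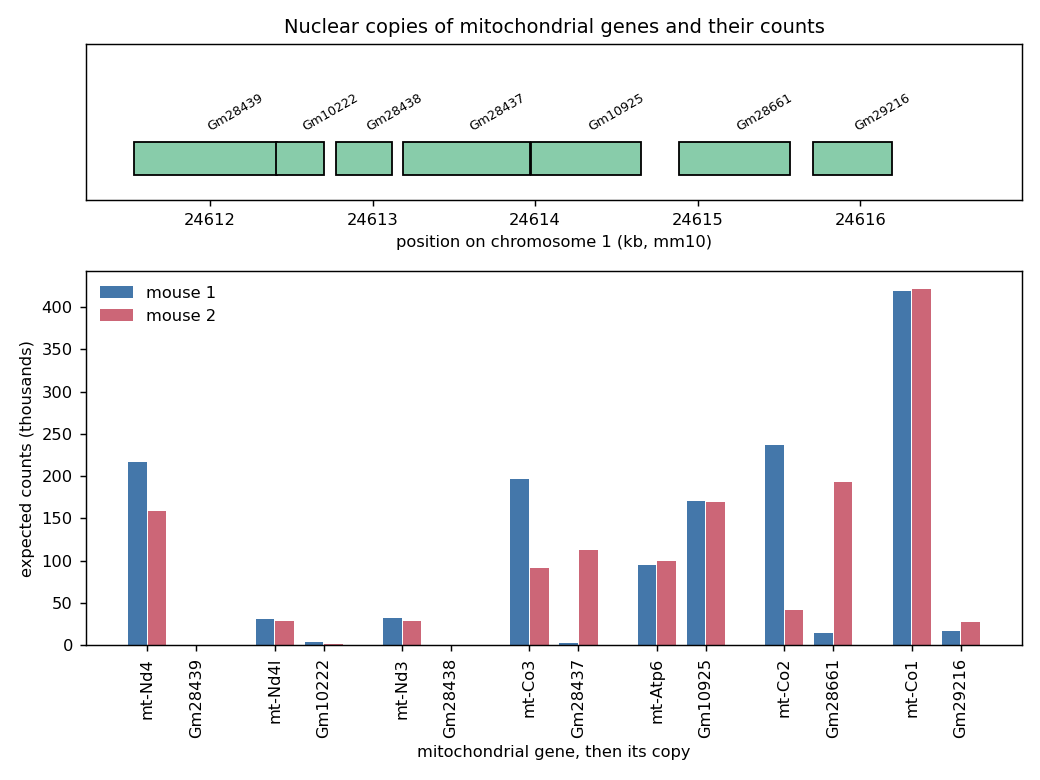
Upper panel, positions on chromosome 1 (kb, mm10) of the copies of mitochondrial genes. Lower panel, expected counts (axis in units of 1000) of each mitochondrial gene and its copy, with mouse 1 in blue and mouse 2 in red. mt-Co2 and mt-Co3 are lower and their copies Gm28661 and Gm28437 higher in mouse 2.

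The third comparison set the 2 quantifications of each library side by side. Small structural RNAs differed most. Snora73a, Snora74a and Snord15b, small nucleolar RNA genes, were listed at 558 ± 123, 688 ± 10.4 and 902 ± 96.7 TPM in the first and at 0 in the second. Rprl3 stood at 595 ± 40.4 TPM in the first. In the other direction, Rpl27 stood at 26.1 ± 3.37 TPM in the first and at 124 and 138 TPM in the second, and Cycs at 11.3 ± 3.87 TPM against 46.3 and 60.7 TPM. Among 13524 genes with a mean of at least 1 TPM, 96 were at least 2-fold higher in the second and 559 at least 2-fold lower. These held 106 of 12121 nuclear protein-coding genes, 296 of 598 pseudogenes and 210 of 226 small RNA genes.

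For most marker genes 1 transcript led. Cyp21a1-201 took 97.0% ± 0.177 of its gene, Cyp11a1-201 98.0% ± 0.134 and Chga-201 97.8% ± 0.021. Star was split between Star-202 at 54.5% ± 2.13 and Star-201 at 45.5% ± 2.13. App was split between App-202 at 48.1% ± 3.51 and App-203 at 43.9% ± 3.74. Hsd3b1-201 took 68.3% ± 7.01. Th-201 took 100% in both mice, against 85.7% on average in the second quantification, and Nr5a1-201 took 79.5% ± 1.57 against 70.8%.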

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

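Rows that no comparison used were flagged where they held more than the 3 counts that a count of 0 allows in 1 row. The phiX row, the sequencing control, held 354 counts in mouse 1 and 238 in mouse 2. The 26248 numbered rows together held 6.75 expected counts in mouse 1 and 2.76 in mouse 2. These are sums over many rows, to which the bound for 1 row does not apply. With 2 mice, no search for samples far from the others could be made.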

How the results depend on the processing

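The filter on posterior SD was chosen after seeing the data, and the other alternatives before. The genes at least 2-fold higher in mouse 2 numbered 1344 without a count filter, 28 at a mean of at least 100 counts, 112 among nuclear protein-coding genes and 127 where the posterior SD was at most 10%. Those at least 2-fold lower numbered 1310, 37 and 141 under the first 3 of these. Fewer or more genes were tested there by construction. The other scalings, the prior count and the second quantification kept both counts within 1.5 times, but a count does not say which genes. In the second quantification, 95 of the 204 higher and 154 of the 319 lower genes were again 2-fold apart in the same direction. The biological coefficient of variation was 0.117 under total count scaling, 0.115 without a filter, 0.104 at 100 counts, 0.105 in the second quantification, 0.0903 among nuclear protein-coding genes and 0.0909 under the posterior SD filter, and the cause was not tested. The count of genes beyond counting noise stayed within 1.5 times.

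Under total count scaling the list medians were -0.0032 for the amyloid pathway, 0.048 for the female and Y-linked list, which rests on Xist alone, and -0.074 for ribosomal proteins, since that scaling moved the median of all genes to 0.05. The other lists of 6 or more tested genes kept their medians within their intervals. Shorter lists have no such interval: kidney went from -0.57 to -0.02 and skeletal muscle from -0.30 to -0.74 in the second quantification, and liver and pancreas from -0.06 to 0.10 without a filter. The 10 most abundant genes took 60.9% of TPM in the second quantification and 8.97% among nuclear protein-coding genes. At 10 TPM, 6131 genes were detected, and 283 genes were 2-fold apart between the quantifications at a mean of at least 10 TPM.

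Of the 148 named genes, 74 moved by more than 1 SD in the second quantification, 31 up and 43 down, as did 8 of 13 leading transcripts, 3 up and 5 down. In FPKM 46 of the 148 moved, all up, and rescaling to nuclear protein-coding genes raised all 125 that it covers. Both change the scale. Of the 29 list median TPM values, 16 moved in the second quantification, 7 up and 9 down, 10 in FPKM and all 29 under that rescaling, all up. Without mouse 1, 13 moved, 3 up and 10 down, and without mouse 2, 6 moved, 2 up and 4 down. With 2 mice, the value of each mouse alone always lies within 1 SD of their mean, so that check says nothing of stability for a single gene. Differences between the mice have no value without a mouse. The prior count does not enter the binomial test or the dispersion. No paired analysis was possible because there was 1 group.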

Other observations

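Gene lists added after the data were examined described further groups. Brown fat genes had a median log2 ratio of 0.70, with all 10 tested members above 0, and fat synthesis genes 0.59, with 12 of 14 above 0. The upper bound of the brown fat interval, 1.20, is the ratio of Ppargc1a, already named among the largest ratios. Lists that hold genes seen to be high are no separate support for a shift. Fasn stood at 0.96 and Thrsp at 0.90, while Acly stood at -0.02. Mesothelium genes had a median of -0.58, with 9 of 10 below 0 and C3 at -1.10. B lineage genes had a median of -0.68, but 4 of 10 members lay above 0, with Cd79a at -2.21 and Ighm at 0.40. Neutrophil and platelet genes had a median of -0.30 over 4 tested members. Most genes of these last 3 lists were scarce. The median level was 0.81 TPM for mesothelium, 0.485 TPM for B lineage and 0.26 TPM for neutrophils and platelets. At 1 TPM in both mice were 4 of 10, 3 of 11 and 2 of 10 genes.

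The tests below were chosen after the results were seen, except those of GC content and length and that of chromosome medians. The design gives 1 group and so names no biological difference to test. The tests concern scaling, sequence content, shared reads, other tissue and handling, and 1 hypothesis of a genetic difference.

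Immediate early genes were lower in mouse 2, as were red blood cell genes. Scaling does not account for it, as the list median was still -0.64 under the scaling nearest to 0, nor do GC content and length, with -0.71 after their removal. Less blood stays open for the list as a whole, as the list median lay above the haemoglobin ratio of -1.05. For 3 of 18 members, Fos (-3.15), Junb (-2.72) and Egr1 (-2.44), the whole counting interval lay below that ratio. A fall of blood by the haemoglobin ratio would not alone lower a gene that far. These values argue against less blood as the whole cause for these 3 members only, which are those that fell most. A stress that also shifts the heat shock list as a whole is argued against by its median of -0.068. The interval over its genes was -0.12 to 0.12, and none of the 12 members was 2-fold apart. A median cannot exclude a smaller induction of a few members. A stimulus around dissection without heat shock, or a difference in the animals, may lie behind it and stays open.

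Adipocyte genes were higher in mouse 2. Scaling (0.68 nearest to 0) and GC content and length (0.69) do not account for it. More fat around the gland is a candidate explanation. All 15 adipocyte genes outside the fixed list were higher, with a median of 0.57, but they were listed after the data were seen. Whether a fat share explains every member's shift cannot be told apart from a change within fat cells, since the heterogeneity per degree of freedom was 97.0 with counting error alone and 0.64 with the spread between mice added. Of the fixed list, 10 of 11 genes reached 1 TPM in both mice, with Cfd and Fabp4 the most abundant.

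For mt-Co2 and mt-Co3, reads shared with their copies on chromosome 1 may account for the opposite shifts. The sum of mt-Co3 and Gm28437 had a log2 ratio of 0.17, the farther from 0 of both pairs, and that of mt-Co2 and Gm28661 0.04.

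A genetic difference between the mice was examined as a hypothesis. The chromosome median farthest from 0 was 0.034, which decides nothing, since alleles can move genes of a chromosome both ways. Across 11713 pairs of neighbouring genes, which are not independent replicates, log2 ratios had a correlation of 0.063, above the shuffled range of -0.018 to 0.018. Over 424 pairs more than 1000000 bases apart it was -0.023, within -0.094 to 0.091, so the hypothesis stays open.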
